A study of Drosophila melanogaster with 3 samples.

How the data were processed

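Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos, 4 to 14 hours old per the labels, from a transgenic line that carries gooseberry-neuro (gsb-n) fused to green fluorescent protein. Gsb-n is a Pax transcription factor with a paired domain and a homeodomain. The precipitation used an antibody against the fluorescent protein, and the chromatin was sonicated to 200 to 800 bp, per the labels. The 3 samples are biological replicates 1, 2 and 3 of this 1 group. An age tag of the labels holds a number that cannot be an embryo age in hours, so the age comes from the source description. Sex was not recorded. No control sample is among the samples used here (a shared control entered the pooled peak calling), so no value can be set beside a background measured the same way.

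The analysis starts from 5 deposited peak lists on the dm6 genome. Each replicate has its own list of 30000 peaks. A pooled list of 30000 peaks was made from the alignments of all 3 replicates and a shared control, per the deposited notes. The last list holds the 5746 peaks kept at an irreproducible discovery rate (IDR) threshold, which rests on how well replicates rank the same peaks. It was made from the replicate and pooled lists, per the deposited notes. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal column holds each peak's height on the authors' scale, which differs between the deposited lists. It was used only to rank and describe peaks within a list. The deposited −log10 q column was used only to describe the lists, the p column holds no p-values, and the summit offset column gave each peak's summit. The lists are relaxed: each was filled to the same 30000 peaks, so their length says nothing about enrichment. Signal tracks named in the deposited notes were not analysed here. No list gives read counts, so the depth of each replicate is unknown and intervals on shares of peaks cover counting error only.

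All 5746 IDR peaks occur unchanged in the pooled list and are its 5746 highest by signal, so the 2 lists are not independent. The IDR list is thus a cut of the pooled list by signal, and its peaks were not each found in every replicate. In the full replicate lists, 64 IDR peaks had a summit within 100 bp in only 1 replicate and 1 had it in none. Peaks that share an interval but have different summits (19 in the IDR list, 31 in the pooled list) were kept. Analyses used chromosome arms 2L, 2R, 3L, 3R, 4 and X. Genes came from Ensembl release 115 (13945 protein-coding genes on these arms) and sequence from the RefSeq copy of genome release 6, the assembly also named dm6. No peak extends beyond the end of an arm in that assembly.

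Replicates were compared through the top 5746 peaks of each list, counting a peak as shared when summits lay within 100 bp, against 1000 circular shifts of 1 list along each arm (permutation test, one-sided, 0.000999 the smallest p possible). Signal was compared across IDR peaks matched in both replicates by Pearson's r of log10 signal and Spearman's rho, with 100000 resamples, whose smallest p is 1e-05. Each summit was classed as within 500 bp of a transcription start site (TSS), other exon, intron or intergenic, in that order, and tested against 1000 circular shifts (two-sided permutation test). Arms were tested with exact binomial tests. For gene lists, each IDR summit was assigned to the protein-coding gene with the nearest TSS, and a gene with at least 1 assigned peak is called bound below. The number of bound members was compared with 10000 random lists matched on decile of territory length, the stretch of genome nearest to a gene's TSS (two-sided permutation test, 0.0002 the smallest p possible). Motif matches on either strand were counted in 201 bp windows at summits and in a window centred 1000 bp to a randomly chosen side, leaving out windows within 300 bp of another IDR summit (exact McNemar test, two-sided). All hexamers, with both strands merged, were counted the same way with Fisher's exact test. P-values were adjusted by Benjamini-Hochberg within each family (4 classes, 6 arms, 27 gene lists, 17 motifs, all hexamers), with 0.05 as the threshold. Peaks and neighbouring genes are not independent of each other, so these p-values describe the lists, not new embryos.

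The tests, alternatives, 27 gene lists and 17 motifs were chosen before the data were examined. Older gene symbols were matched to the annotation by a table written afterwards, and 1 listed name, ladybird, matched no gene. Genes belong to more than 1 list in places, and the list called general chromatin factors below holds Trl, psq, lola, ph-p and other chromatin regulators. Named genes are the nearest genes of the 15 highest IDR peaks, the 10 genes with the most IDR peaks, up to 3 members of each list with the most peaks, and, whatever their values, gsb, gsb-n, prd, wg, en, ftz and eve. Not all of these are named below. Alternatives covered the matching distance, the number of top peaks, promoter and motif window sizes and assignment rules. They also covered the background and the stronger part of the IDR list. Sets described as without replicate 1, 2 or 3 are the IDR peaks found among the top peaks of both other replicates. They hold 3779, 3596 and 3915 peaks of an IDR list that still rests on all 3 replicates. A call that ends in such a smaller set thus does not show dependence on the named replicate. Comparisons with peaks drawn from the pooled list, with dinucleotide-shuffled windows, with TSS-proximal peaks alone and with flanks on 1 fixed side were added after seeing the data. The pooled draws include the IDR peaks and weaker peaks of the same precipitation. A call that ends against them thus does not argue against binding at a list. The draws of gene lists from the pooled list were first made 1000 times and then, after the ribosomal protein list had missed the threshold, 10000 times, because 1000 draws could not give an adjusted p under the threshold for a single list. The steps were tested on simulated data. Of 20 gene lists with 85% of members bound, 100% were called, and of 200 unchanged lists 2.5% were. These calls used unadjusted p-values. Simulated genes were bound independently of their neighbours, at rates set by the same territory deciles that the test matches on. The gene list check therefore does not cover lists of neighbouring genes or smaller shares bound. The motif GTCACGS planted in 10% of windows was called in 100% of 20 sets, and unplanted sets in 5%. Simulated summit and flank windows had the same base composition, so this check does not cover the lower GC content of real summits. With 60% of 5000 simulated peaks shared, the overlap step returned 59.9%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.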

Results

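The data are maps of where the tagged Gsb-n protein was recovered on the genome of whole embryos. Gsb-n acts in the embryonic nervous system, next to its neighbour and paralogue gooseberry (gsb), a segment polarity gene. The 3 biological replicates of 1 group each gave 30000 relaxed peaks covering 11.2, 10.6 and 10.8 Mb, or 8.39%, 7.93% and 8.08% of the arms. The IDR list held 5746 peaks with a median width of 416 bp, covering 2.04 Mb (1.52%). The design has no second group, so the comparisons are between replicates, between bound and unbound genes, and between peaks and the rest of the genome. Coordinates are dm6.

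The 3 replicates marked largely the same sites. Replicates 1 and 2 shared 69.1% of their top 5746 peaks, replicates 1 and 3 shared 64.7%, and replicates 2 and 3 shared 68.0%. Circular shifts gave 0.869%, 0.870% and 0.872% (permutation p = 0.000999 for each of 3 pairs, the smallest possible). Among the top 1000 peaks, 78.9%, 76.6% and 81.5% were shared. The IDR list contained 3261 peaks (56.8%) found among the top 5746 of all 3 replicates, 1507 found in 2, 865 in 1 and 113 in none. Of the strongest 1437 IDR peaks 97.1% were in all 3 replicates' top peaks and of the weakest 1436 3.97%, a trend built in, at least in part, by taking the same number of top peaks from the pooled and the replicate lists. Against the full replicate lists, 5135 IDR peaks (89.4%) had a summit in all 3. Across IDR peaks, which are not independent replicates, signal correlated between replicates 1 and 2, 1 and 3, and 2 and 3 (5344, 5264 and 5343 matched peaks). Spearman's rho was 0.725, 0.711 and 0.746 and Pearson's r was 0.784, 0.772 and 0.807. The permutation p was 1e-05, the smallest possible, for each of 6 coefficients before and after adjustment. The IDR list was made from these same replicates, so the correlation is no separate evidence that they agree.

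**Figure D1:**
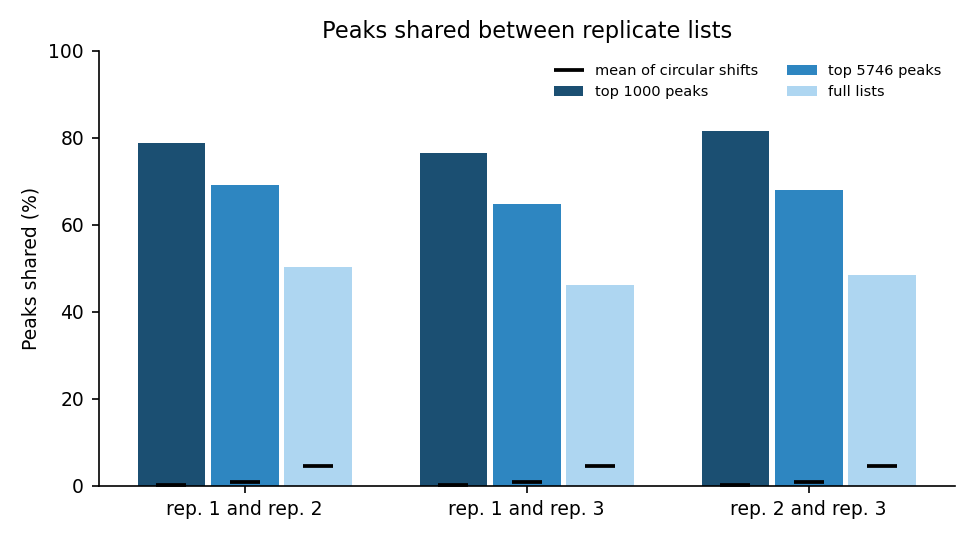
Share of peaks (%) with a summit within 100 bp in the other replicate's list of the same length, for each pair of replicates; bars are the top 1000 peaks, the top 5746 peaks and the full lists, and black lines are the mean of circular shifts. All bars stand far above the shifts, and the share falls as lower-ranked peaks enter, from 78.9% to 50.2% for replicates 1 and 2.

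Gsb-n peaks lay at promoters more often than chance and hardly ever in other exons. Of the IDR summits, 35.3% (2031) were within 500 bp of a TSS, against 11.4% after circular shifts (3.09-fold, adjusted permutation p = 0.00266). Other exons held 1.34% (77) against 19.2%, and intergenic sequence held 24.9% (1429) against 30.1%, with the same adjusted p. Introns held 38.4% (2209) against 39.2% (adjusted permutation p = 0.5). In the replicates' own top 5746 peaks the TSS share was 38.1% ± 3.89 (SD, n = 3) and the intron share 36.6% ± 2.88 (SD, n = 3), with replicate 3 at 42.6% and 33.3%. Promoter peaks were also slightly stronger: the median signal was 267.2 within 500 bp of a TSS and 244.3 elsewhere, a difference of 22.9 (two-sided permutation p = 1e-05, the smallest possible), and 57 of the 100 strongest peaks were at a TSS. Peaks drawn at random from the pooled list, which contains the IDR peaks, had a TSS share of 21.1%, and its other peaks alone 17.7%. Part of the promoter share is therefore common to the relaxed peaks.

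Chromosome arms differed in peak density. Arm 2L had 49.8 IDR peaks per Mb, 1.16 times the number its length predicts (adjusted exact binomial p = 2.79e-07), and 3L had 45.8 (1.07 times, adjusted exact p = 0.0104). Arms 2R and X had 38.7 and 38.4 (0.901 and 0.895 times, adjusted exact p = 0.000407 and 0.000389), and 3R had 43.0 (1.00 times, adjusted exact p = 0.975). The small, gene-poor chromosome 4 had 28 peaks, 20.8 per Mb (0.484 times, adjusted exact p = 6.33e-05). Counted per protein-coding gene, the calls for 4 (0.849 times, adjusted exact p = 0.518) and X (0.999 times, adjusted exact p = 0.986) ended.

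The strongest Gsb-n peak in every replicate was at plexus (px), which acts in wing vein patterning. It spans 2R from 22514119 to 22514501, 200 bp from a TSS, with a signal of 3712. It was followed by CG14100 (signal 2920), CG11050 (2876), the mitochondrial ribosomal protein gene mRpS10 (2816), Fkbp14 (2628), CG18549 (2571), CG31668 (2527), the zinc-finger gene cabut (cbt, 2467), the Polycomb group gene Posterior sex combs (Psc, 2446) and RluA-1 (2401). Chromator (Chro, 2397), CG5611 (2263), CenG1A (2256), Ugalt (2250) and hll (2215) complete the 15 highest peaks. Ranks of these peaks were close between replicates: mRpS10 was at rank 4 ± 1 (SD, n = 3), Psc at 10.3 ± 5.13 (SD, n = 3) and Chro at 9.33 ± 3.06 (SD, n = 3). The 15 peaks were picked as the highest of a list made from the same replicates, so high ranks in each are partly built in. No signal in these lists separates binding by Gsb-n from signal that other tagged proteins would also give at these sites.

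Some genes were nearest to many peaks. In all, 3080 of 13945 protein-coding genes (22.1%) were nearest to at least 1 IDR peak, and 27 genes had 10 or more. Homothorax (hth), a homeobox cofactor of Hox proteins, had the most (23), all over 500 bp from a TSS, and its strongest had a signal of 752.6 at rank 441 ± 333 (SD, n = 3). The nuclear receptor gene Eip75B, CG43245 and the translational repressor gene pumilio (pum) had 15 each, and RapGAP1 had 14. The ETS factor gene pointed (pnt), the zinc-finger gene noc, CG42238, the forkhead gene CHES-1-like and the kinase gene Tlk had 13 each. Long territories gather peaks (133.9 kb for hth), and the nearest TSS may not be the regulated one: 849 peaks (14.8%) were over 10 kb from it.

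Segmentation genes were bound widely, though prd was not. All 14 segment polarity genes were bound, against 6.41 in matched random lists (adjusted permutation p = 0.00108), and 14 ± 0 (SD, n = 3) in the replicates' own top peaks. Wingless (wg), the Wnt ligand that Gsb maintains in the epidermis, had 5 peaks, the strongest with signal 661.0 at 2L from 7295953 to 7296301, 10989 bp from the TSS in intergenic sequence. Engrailed (en) had 5 peaks with a top signal of 536.0, H15 had 8 and the Wnt receptor gene fz2 had 8. Of the pair-rule genes, 8 of 10 were bound against 4.05 (adjusted permutation p = 0.0498, at the edge of the threshold), led by sloppy paired 2 (slp2, 6 peaks, top signal 1245), opa (4) and slp1 (3). Even skipped (eve) had 3 peaks (top signal 454.5) and ftz had 2 (405.4), while prd, the founding paired-class gene, had none of the IDR peaks and none of the 30000 pooled peaks. All 8 Hox genes were bound, 2.11 times the number in matched lists (adjusted permutation p = 0.013), with 9 peaks at Antp (top signal 1414), 7 at abd-A and 4 at Abd-B. Of the gap and head gap genes, 9 of 12 were bound against 5.27, which did not pass (adjusted permutation p = 0.0918); ems and oc had 5 peaks each and btd had 3. Among Pax and paired-like homeobox genes 12 of 18 were bound against 6.89 (adjusted permutation p = 0.0453, near the threshold), 12.7 ± 1.15 (SD, n = 3) by replicate, with gsb, gsb-n and Ptx1 (5 peaks) highest. Gsb-n is the tagged gene and gsb, which is also in the segment polarity list, is its neighbour. Their peaks may reflect extra copies of the locus, and neither list was tested without them. Against draws from the pooled list the pair-rule and Pax calls ended (1.04 and 0.931-fold, adjusted permutation p = 1 for both). The segment polarity and Hox lists could not pass there, because draws already bound 13.7 of 14 and 7.41 of 8 members. These draws hold IDR peaks and weaker peaks of the same precipitation, so a lost call does not show a lack of binding. When only peaks within 1 kb of a TSS were assigned, segment polarity (2.47-fold, adjusted permutation p = 0.0603), Pax (2.16-fold, p = 0.109) and pair-rule genes (1.87-fold, p = 0.44) no longer passed although their folds stayed near or above the main 2.19, 1.74 and 1.98, and Hox genes fell to 1.05-fold (p = 1).

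Among genes of the nervous system, regulators of neuronal identity were bound and genes of mature neurons were not called. Of 17 neuronal identity factors 16 were bound against 6.82 (adjusted permutation p = 0.00108), 15.3 ± 0.577 (SD, n = 3) by replicate: jing had 11 peaks, tailup (tup, a LIM-homeobox gene of motor neurons) 9 and the POU gene ventral veins lacking (vvl) 7. The neuroblast and proneural list had 14 of 23 against 9.37 (adjusted permutation p = 0.119), with 6 peaks at Dr and 5 at SoxN, and axon guidance genes had 16 of 24 against 10.7 (adjusted permutation p = 0.0774), with 9 at Sema1a and 7 at comm. Axon guidance genes passed when peaks in gene bodies or within 2 kb were assigned (1.65-fold, adjusted permutation p = 0.0345). Glial genes had 6 of 12 against 3.33 (adjusted permutation p = 0.233). Genes of terminal neuronal differentiation had 5 of 19 against 6.81 (adjusted permutation p = 0.564), with 2 peaks at the RNA-binding protein gene elav (top signal 1221). The neuromuscular junction and synaptic homeostasis list, relevant because Gsb acts in synaptic homeostasis, had 3 of 14 against 3.91 (adjusted permutation p = 0.867): Ank2, Dysb and dlg1 had 1 peak each. The neuronal identity call ended against draws from the pooled list (1.23-fold, adjusted permutation p = 0.261).

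Genes of other tissues and of signalling pathways were bound as well. The chromatin came from whole embryos, so the tissue in which a gene was bound is unknown. All 12 endoderm and midgut genes were bound against 4.83 (adjusted permutation p = 0.00108), with 7 peaks at the forkhead gene fkh and 4 at sog. In the mesoderm and muscle identity list 15 of 23 were bound against 8.60 (adjusted permutation p = 0.0252), with 11 peaks at kirre and 6 at lbl, and in the trachea list 10 of 13 against 5.17 (adjusted permutation p = 0.0252), with 9 at apt. The Notch pathway and E(spl) complex list had 15 of 21 against 5.04 (adjusted permutation p = 0.0018), including neur (4 peaks) and E(spl)m3-HLH (3), the Wnt list 13 of 18 against 6.70 (adjusted permutation p = 0.012), including nkd (6), and the EGFR, FGF and TGF-beta list 17 of 22 against 9.01 (adjusted permutation p = 0.00231), including aop (8) and aos (6). Muscle structural genes (3 of 15 against 4.67, adjusted permutation p = 0.564), hemocyte and fat body genes (6 of 11 against 3.51, adjusted permutation p = 0.267) and epidermal denticle and cuticle genes (9 of 16 against 6.08, adjusted permutation p = 0.287) did not pass. All 6 calls ended against draws from the pooled list (0.981 to 1.28-fold, adjusted permutation p from 0.212 to 1). Those draws mix the IDR peaks with weaker peaks of the same precipitation, so they cannot separate weaker binding from background. With peaks within 1 kb of a TSS the Notch call held, and the others did not pass at folds of 2.13 (trachea, main 1.94), 1.88 (EGFR, FGF and TGF-beta, main 1.89), 1.93 (endoderm, main 2.49), 1.62 (Wnt, main 1.94) and 1.496 (mesoderm, main 1.74). The trachea call also ended without replicate 2 or 3 (1.70 and 1.62-fold, adjusted permutation p = 0.232 and 0.322). Without replicate 3 those for Wnt genes (1.82-fold, adjusted permutation p = 0.0895) and Hox genes (1.87-fold, p = 0.185) ended. The sets without a replicate hold fewer IDR peaks, so these lost calls do not show dependence on that replicate.

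Ribosomal protein genes were bound more often than matched genes, as were genes with abundant embryonic mRNAs, a list written after the main results were seen (12 of 23 against 4.39, permutation p = 0.0004), while proteasome genes were not called. Of 92 cytoplasmic ribosomal protein genes 57 were bound against 15.2 (3.76-fold, adjusted permutation p = 0.00108), and 60 ± 4.58 (SD, n = 3) in the replicates' own top peaks. All 57 had a peak within 500 bp of a TSS; the strongest was at RpL7 (signal 893.7), and RpS23 had 3 peaks and RpLP2 had 2. This list alone passed against draws from the pooled list (19.2 expected, 2.96-fold, adjusted permutation p = 0.0054 with 10000 draws; 0.0539 with 1000). Proteasome subunit genes did not pass (4 of 43 against 6.55, adjusted permutation p = 0.439; Rpn3, Rpn6 and Rpn13 had 1 peak each), nor did cell cycle genes (6 of 19 against 4.03, adjusted permutation p = 0.439; E2f1 had 6 peaks) or testis-specific genes (5 of 22 against 4.85, adjusted permutation p = 1; Mst87F and bol had 2 each). General chromatin factor genes were bound in 9 of 12 cases against 3.86 (adjusted permutation p = 0.012), with 7 peaks at psq, 4 at the GAGA factor gene Trl (top signal 1950) and 4 at the Polycomb group gene ph-p (top signal 2195); this call ended against draws from the pooled list (adjusted permutation p = 0.267). Odorant and gustatory receptor genes were bound less often than matched genes, 7 of 119 against 26.2 (adjusted permutation p = 0.00108), a call that also ended against the draws (adjusted permutation p = 0.212). In all, 13 of 27 lists were bound more often than matched genes and 1 less often.

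**Figure D2:**
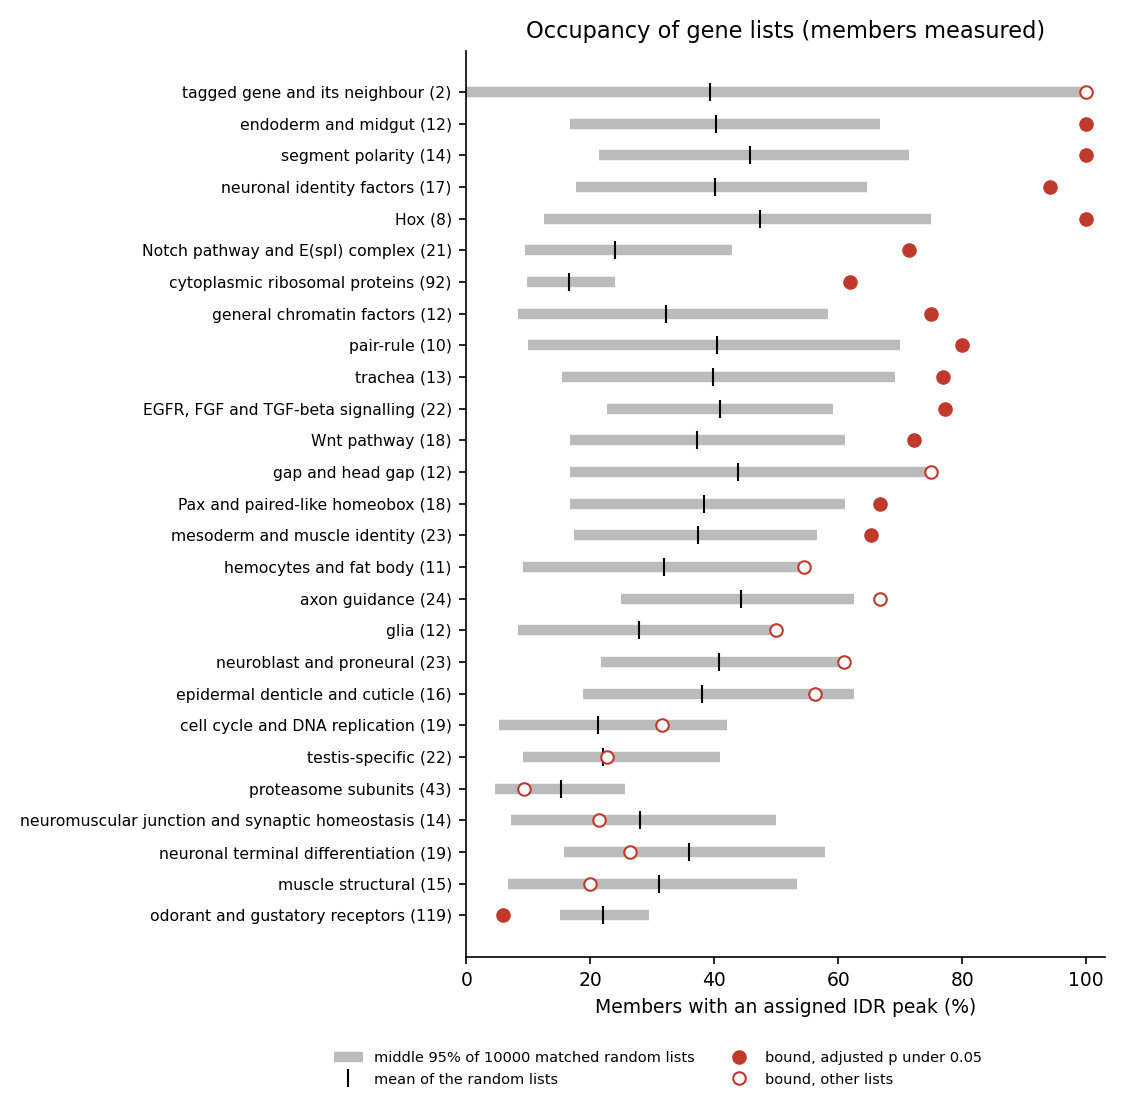
Share of each list's members (number in brackets) with at least 1 assigned IDR peak (%, circles), with the middle 95% (grey bars) and mean (ticks) of 10000 random lists matched on territory length; filled circles passed the adjusted threshold. The 13 filled circles to the right of their bars include 57 of 92 ribosomal protein genes, and receptor genes lie to the left with 7 of 119.

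Of the sites known for paired-class proteins, the homeodomain sites and the core GTCACGS were more frequent at summits than in flanks. The homeodomain core TAATTA was in 17.4% of 5697 summit windows (95% Wilson interval 16.4 to 18.4) and 13.0% of flank windows (12.1 to 13.9), a 1.34-fold excess (adjusted exact McNemar p = 3.81e-10). The paired-class dimer TAATNNNATTA was in 2.91% against 1.76% (1.66-fold, adjusted exact p = 0.000141), the shorter dimer TAATNNATTA in 2.58% against 1.53% (1.69-fold, adjusted exact p = 0.00024) and the paired-domain core GTCACGS in 2.67% against 1.79% (1.49-fold, adjusted exact p = 0.00435). The other paired-domain core, GTTCCS, was rarer at summits, 8.83% against 11.1% (0.797-fold, adjusted exact p = 0.000176), and the composite of ATTA and GTTCC did not pass (0.386% against 0.193%, adjusted exact p = 0.109). Without 1 replicate the fold of TAATNNNATTA ranged from 1.78 to 2.64, highest without replicate 2. In the replicates' own top peaks TAATTA was in 17.2% ± 1.39 of windows and TAATNNNATTA in 2.96% ± 0.168 (SD, n = 3). TAATTA was also more frequent in the strongest 1436 IDR peaks (19.7%) than in the weakest 1436 (14.7%, adjusted Fisher's exact p = 0.00747); the comparison of the stronger with the weaker 2873 peaks did not pass (adjusted exact p = 0.0774). There the M1BP element passed as less frequent in the stronger peaks (1.08% against 2.19%, adjusted exact p = 0.0196). The GTCACGS call ended without replicate 1 or 2 (adjusted exact p = 0.0529 and 0.136) and the GTTCCS call without replicate 1 or 3 (adjusted exact p = 0.0529 and 0.173). Those sets hold fewer IDR peaks, so the lost calls do not show dependence on the named replicates. Summit windows had a lower GC content than flanks (37.1% against 42.1%), and over dinucleotide-shuffled summit windows TAATTA (0.96-fold, adjusted exact p = 0.339) and TAATNNATTA (1.19-fold, adjusted exact p = 0.207) did not pass, while TAATNNNATTA did (1.69-fold, adjusted exact p = 9.32e-05).

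Promoter elements of broadly expressed genes gave the highest folds. The DREF element TATCGATA was in 2.65% of summit windows against 0.439% (6.04-fold, adjusted exact McNemar p = 3.05e-22) and the M1BP element GGTCACACT in 1.60% against 0.158% (10.1-fold, adjusted exact p = 2.82e-17). Without 1 replicate they ranged from 4.58 to 6.63-fold and from 8.17 to 15.7-fold, and in TSS-proximal peaks they were at 15.3 and 28.7-fold. In peaks over 500 bp from a TSS they were at 1.08-fold (adjusted exact p = 1) and 0.714-fold (adjusted exact p = 0.823). Flank windows lay 1000 bp away and promoters without a peak were not compared. The DREF and M1BP folds may therefore follow from the position of peaks at a TSS alone. GATA sites (17.7% against 14.4%, adjusted exact p = 3.69e-06) and GAGA repeats (4.46% against 3.42%, adjusted exact p = 0.00806) were more frequent at summits, and CATMTG E-boxes less (13.3% against 15.2%, adjusted exact p = 0.00664). The GATA excess ended over shuffled windows (1.02-fold, adjusted exact p = 0.688) and in TSS-proximal peaks (1.11-fold, adjusted exact p = 0.217). The GAGA excess ended with narrower windows (1.01-fold, adjusted exact p = 1), with flanks 500 bp away (1.02-fold, adjusted exact p = 0.87), in the stronger part of the IDR list (1.08-fold, adjusted exact p = 0.664), in distal peaks (1.19-fold, adjusted exact p = 0.231) and without each replicate in turn (1.08 to 1.25-fold). Over shuffled windows it was 3.63-fold (adjusted exact p = 4.15e-29). The CATMTG call ended at folds near the main 0.873 with narrower windows (0.885-fold, adjusted exact p = 0.129), flanks 500 bp away (0.907-fold, 0.0537), distal and TSS-proximal peaks apart (0.907 and 0.839-fold, 0.185 and 0.0654) and without replicate 2 (0.877-fold, 0.0555). Over shuffled windows it passed in the opposite direction (1.21-fold, adjusted exact p = 0.000481). Zelda, CAGCTG, Su(H), Sox, POU and TCF sites did not pass in the main analysis, with folds from 0.912 to 1.02. Under alternatives CAGCTG passed as less frequent in distal peaks (0.754-fold, adjusted exact p = 0.00388), in the stronger peaks (0.775-fold, 0.0109), without replicate 3 (0.811-fold, 0.0227) and with left flanks (0.838-fold, 0.00767), but as more frequent over shuffled windows (2.71-fold, 3.9e-31). Sox passed as less frequent over shuffled windows (0.751-fold, adjusted exact p = 0.000546). So did Su(H) with flanks 500 bp away (0.765-fold, adjusted exact p = 0.00784) and Zelda with those (0.723-fold, 0.00868) and with right flanks (0.765-fold, 0.0412). Among hexamers 438 were more and 878 less frequent at summits, led by ACACTG (14.8% against 7.27%, 2.04-fold, adjusted Fisher's exact p = 3.3e-36), ACAGTG (1.96-fold) and CGATAG (1.89-fold); 125 were also above shuffled windows.

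**Figure D3:**
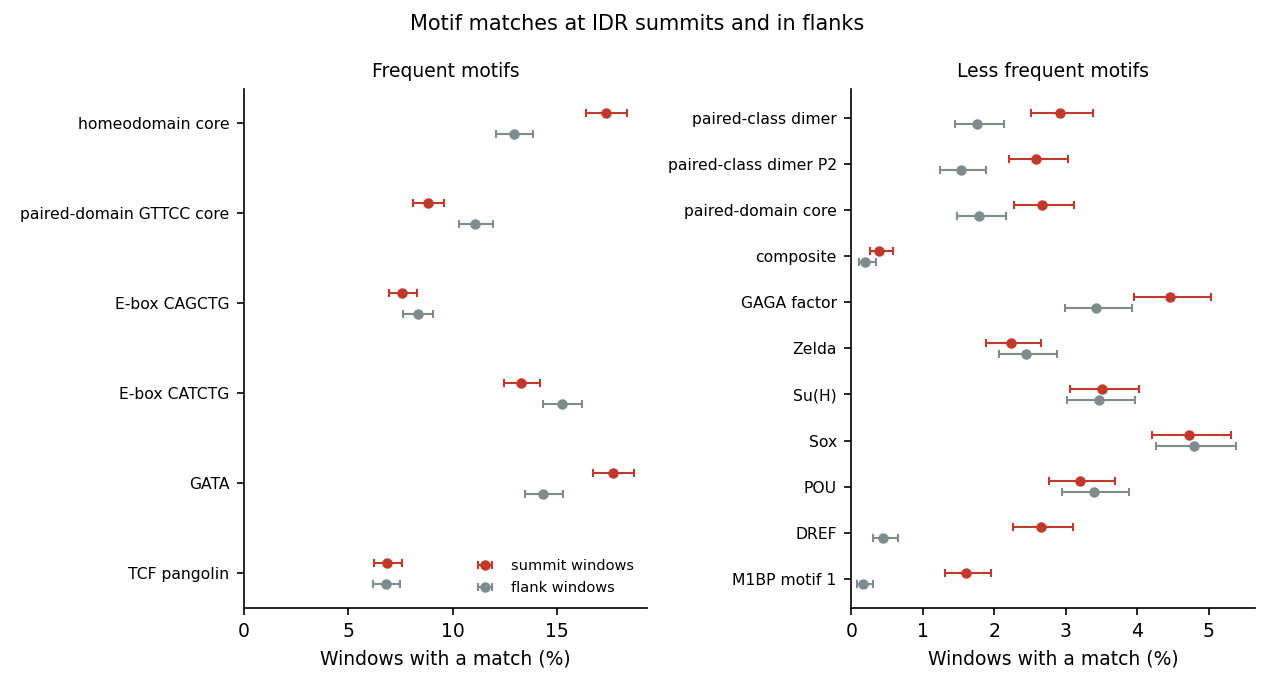
Share of 5697 summit windows (red) and flank windows (grey) with a match to each motif (%), with 95% Wilson intervals that cover counting error only; frequent and less frequent motifs have separate scales. TAATTA stands at 17.4% against 13.0%, and the DREF and M1BP promoter elements at 2.65% and 1.60% against 0.439% and 0.158%.

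The locus of the tagged gene itself was densely occupied. Within 20 kb of gsb-n and gsb (2R from 25020383 to 25084643) there were 17 IDR peaks, or 2.65 per 10 kb against 0.429 over the arms; the replicate lists had 48, 53 and 52 peaks there and the pooled list 55. Of the windows of the same length that tile the arms, 4 (0.192%) had as many IDR peaks, and the median window had 2. Gsb-n (gene at 25040383 to 25052331, minus strand) had 7 peaks, the strongest 497 bp from its TSS with signal 942.1, at rank 230 ± 126 in the replicates (SD, n = 3). Gsb (25061964 to 25064643, plus strand) had 8, the strongest at 25068501 to 25068944 in intergenic sequence 6736 bp from its TSS (signal 929.2, rank 251 ± 89.6, SD, n = 3), and another 57 bp from its TSS (signal 908.5). A list of 2 genes is too short for the list test (2 of 2 against 0.786, adjusted permutation p = 0.395), and the labels do not say whether the line carries the locus in extra copies.

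**Figure D4:**
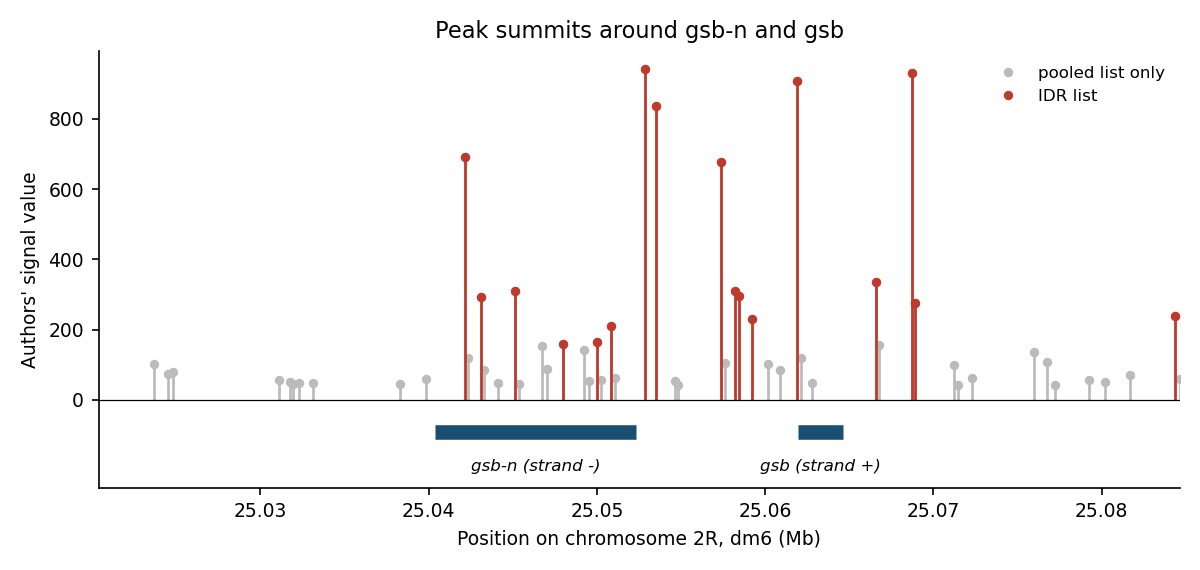
Peak summits along 2R (dm6, Mb) around gsb-n and gsb, with the authors' signal value from the pooled scale; red are the 17 IDR peaks, grey other pooled peaks, and blue bars the annotated genes. The highest peaks lie at the start of gsb-n (942.1), at the start of gsb (908.5) and on the far side of gsb (929.2).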

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

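The signal below was examined only after the peak lists had been seen. Outside the IDR list, the pooled list holds 24254 weaker peaks, and 5312 of them (21.9%) had a summit within 100 bp of a peak in all 3 replicate lists. This was picked out as a signal in data little used elsewhere, with no control sample to set beside it. The pooled list was called on the same 3 alignments, so coincidence with replicate peaks is built in and is no separate evidence of binding. Of these 5312 peaks 19.9% were within 500 bp of a TSS, 45.2% in introns and 31.9% intergenic, and they were nearest to 2700 genes, 1267 of which had no IDR peak. They added genes of many lists, with no test of any: 5 of 23 neuroblast and proneural genes, 5 of 119 odorant and gustatory receptor genes, and 4 each of the axon guidance, glia, muscle structural, ribosomal protein and proteasome lists.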

How the results depend on the processing

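Of 563 alternative values, 425 kept their direction and their side of the threshold or stayed close; the pooled draws, shuffled windows, TSS-proximal peaks and fixed flanks were chosen after seeing the data. No paired analysis was possible because the series has 1 group. All 15 overlap, 6 correlation and 1 strength alternatives kept direction and call; interval overlaps used 100 shifts. The depth of each replicate is unknown, so its effect could not be tested; replicate 3's own peaks had a TSS share of 42.6% against 36.0% and 35.7%. Of the reversed values, 41 had neither value past the threshold. Unless stated, the cause was not tested.

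IDR peaks in all 3 replicates rose to 5135 with full lists, by construction. The intron share passed as lower with a 1000 bp promoter window (33.2%), in replicate 3's own peaks (33.3%) and against pooled draws (38.4%, higher expectation), and was 36.7% to 39.7% without 1 replicate, above expectation without replicate 3. Arm 3R turned to 0.962 in the stronger part of the IDR list and 0.978 per gene, where 4 (0.849) and X (0.999) lost their calls. Lists bound more often fell from 13 to 4 with peaks within 1 kb of a TSS (fewer peaks) and to 1 against pooled draws (where full lists such as segment polarity and Hox could not pass), and there lists bound less often went from 1 to 0.

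Further list calls ended with gene bodies (pair-rule 1.32-fold and trachea 1.803-fold), with circular shifts (pair-rule 1.90, Hox 1.71, trachea 1.81) and in the stronger peaks (Hox 2.29 and Pax 1.99, above their main 2.11 and 1.74, and trachea 1.68). Calls gained were axon guidance with gene bodies (1.65) and, without matching, gap, neuroblast, axon guidance, glia, hemocyte and epidermal genes (2.27 to 3.40). List folds that turned were, with gene bodies and 2 kb, neuronal differentiation 1.29, neuromuscular 1.06 and testis 0.695; within 1 kb, muscle structural 1.095, hemocyte 0.984, epidermal 0.902 and testis 0.599; without matching, neuronal differentiation 1.19; in the stronger peaks, muscle structural 1.02 and testis 0.33; and against pooled draws, Pax 0.93, neuroblast 0.767, axon guidance 0.896, glia 0.917, neuromuscular 1.36, mesoderm 0.981, epidermal 0.872 and proteasome 1.31.

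The paired-domain core lost its call in the stronger peaks (1.32) and in TSS-proximal peaks (1.39), and ranged from 1.36 to 1.49 without 1 replicate, where the calls without replicates 1 and 2 ended. GTTCCS lost it in distal peaks (0.89), against shuffled windows (0.901) and without replicates 1 or 3 (0.857 and 0.896), and kept it without replicate 2 (0.802). Against shuffled windows TAATTA turned to 0.96, the P2 dimer lost its call (1.19), and CAGCTG (2.71), CATMTG (1.21), POU (1.23) and TCF (0.91) turned. The composite passed with left flanks (2.75). Su(H) turned with narrower windows (0.888), flanks 500 bp away (0.765, a call gained), distal peaks (0.884) and without 1 replicate (0.938 to 0.963). Sox turned with narrower windows (1.10), distal peaks (1.20) and left flanks (1.00), and ranged from 0.89 to 1.01 without 1 replicate. POU turned with narrower windows (1.12), distal (1.04) and TSS-proximal peaks (1.13). TCF turned with flanks 500 bp away (0.971), TSS-proximal peaks (0.806) and without 1 replicate (0.956 to 1.09). M1BP turned in distal peaks (0.714) and CAGCTG in TSS-proximal ones (1.04). Motifs more frequent at summits fell from 8 to 5 in distal peaks. Motifs less frequent fell from 2 to 1 with narrower windows, distal peaks, shuffled windows and TSS-proximal peaks, ranged from 1 to 2 without 1 replicate, and rose to 3 with flanks 500 bp away, in the stronger peaks and with left or right flanks. Between the stronger and weaker peaks Zelda (1.13), CATMTG (1.00), POU (0.876) and TCF (1) turned, and M1BP gained a call as lower in the stronger peaks. Hexamers more frequent fell from 438 to 125 when shuffled windows also had to be exceeded.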

Other observations

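The tests on proteasome genes, shuffled windows and the tagged locus were chosen after the result was seen, while the list of abundant mRNAs was written before its genes were looked up. Homeodomain and promoter sites had lower folds in weaker pooled peaks than in the IDR list, while GTCACGS and GAGA repeats did not; the differences were not tested. In 21284 windows at their summits the paired-domain core GTCACGS was in 2.43% against 1.55% of flanks (1.57-fold, adjusted exact McNemar p = 3.73e-10) and GAGA repeats in 4.23% against 2.60% (1.63-fold, adjusted p = 7.12e-20), while TAATTA was at 14.9% against 13.8% (1.08-fold, adjusted p = 0.00582), TAATNNNATTA at 1.94% against 1.64% (1.18-fold, adjusted p = 0.0425) and TAATNNATTA at 1.60% against 1.25% (1.28-fold, adjusted p = 0.0067). In the IDR list these 3 were at 1.34, 1.66 and 1.69-fold, and DREF and M1BP elements were at 6.04 and 10.1-fold there against 3.75 and 6.82-fold in the weaker peaks. Weaker peaks were less often within 500 bp of a TSS (17.7% against 35.3%), and these elements had no excess in distal IDR peaks. Within the IDR list the stronger 2873 peaks were not richer in these elements than the weaker 2873. DREF was in 2.54% against 2.71% (adjusted Fisher's exact p = 0.901) and M1BP in 1.08% against 2.19% (adjusted Fisher's exact p = 0.0196). This argues against peak strength alone as the source of the DREF and M1BP folds within the IDR list. The weaker pooled peaks were not split by location, so for them strength and location cannot be told apart. The densest window of all, 24 IDR peaks at 3R from 5076620 to 5140880, lies around corto, a chromatin factor gene, and a window with 16 peaks at 3R from 25961445 to 26025705 covers part of the E(spl) complex. The hexamer ATCGAT, which lies inside the DREF element, was in 15.6% of TSS-proximal and 5.54% of other summit windows, whereas GTGCAC was in 5.06% and 8.56%.

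Ribosomal protein genes were bound in 62.0% of cases (exact 95% interval 51.2 to 71.9). An equal background at all broadly expressed promoters is argued against by proteasome genes, of which 9.30% were bound (exact interval up to 22.1%). This share was known when the test was chosen, and whether all 43 listed proteasome genes are broadly expressed was not checked. A higher background at the most transcribed genes may account for the pattern: of 23 genes with abundant embryonic mRNAs, such as eEF1alpha1, Act5C, Hsc70-4 and Rack1, 52.2% were bound, 12 against 4.39 in matched lists (2.74-fold, permutation p = 0.0004), all within 500 bp of a TSS. That list was taken from general knowledge and not from expression values. Its bound genes include translation factor genes such as eEF1alpha1 and eEF2. The list therefore cannot separate transcript abundance from other traits that such genes share with ribosomal protein genes. With 1 group and no control sample among those used here, no biological explanation was tested.

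The excess of TAATTA at summits may come from their AT-rich sequence, since its fold over dinucleotide-shuffled summit windows was 0.96. The paired-class dimer TAATNNNATTA was at 1.69-fold over shuffled windows, and the shorter dimer TAATNNATTA at 1.19-fold (adjusted exact p = 0.207). Shuffling cannot settle the explanation for the dimers, because CAGCTG and CATMTG sites also exceeded shuffled windows without an excess over flanks. A candidate explanation for TAATNNNATTA is binding by paired-class homeodomains, of which Gsb-n is 1 among many in the embryo. These lists cannot separate them, and no biological explanation was tested.

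The crowding of peaks at gsb and gsb-n may reflect extra copies of the locus in the transgenic line or binding there. Only 0.769% of windows of the same length had as many pooled peaks (16 windows), though the 55 pooled peaks of the locus include the 17 IDR peaks. The pooled list had 8.56 peaks per 10 kb there against 2.24 over the arms. That is a smaller contrast than 2.65 against 0.429 in the IDR list. Crowding in the relaxed list is what extra copies would give. Binding would give it too, and the ends of the inserted DNA are not given in the sources used here. The explanations cannot be told apart from these peak lists; the signal tracks and control that the deposited notes name were not analysed here, and no biological explanation was tested.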
